A study of Mus musculus with 24 samples.

How the data were processed

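The series holds RNA sequencing of mouse tissue from a surgical model of endometriosis, in which uterine tissue grows outside the uterus. Total RNA came from sham-operated uterus (sham), from the uterus of mice with endometriosis (eutopic) and from endometriotic lesions (ectopic, called lesions here), at 1 month and at 3 months after surgery. All 24 libraries were collected on pregnancy day 3.5, and each of the 6 groups holds 4 libraries.

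The table deposited by the authors holds read counts per gene, in whole numbers, with 1 column per library. Per the submitters' processing notes, reads were handled with bcl2fastq 1.9.0 and STAR 2.7.9a on genome build mm39, and edgeR was used. The annotation release, the counting mode and the strand setting are not given in the sources used here, so counts of overlapping or antisense genes and of close paralogs are uncertain. No sequencing batch or date is given in the labels. The table holds 56691 genes with an identifier, a biotype and a symbol, and no positions. 77 symbols stood on more than 1 line and were kept apart by identifier.

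Total counts ran from 4.51e+07 to 5.94e+07 per library. Intervals and floors that rest on counts cover counting error only. The series text describes 4 mice per group, but the labels do not tie each library to an animal of its own, so each p-value measures the spread between samples. Genotype is labelled with the Cre driver for lesions and without it for eutopic and sham uterus, while the series text gives the driver for the mice with endometriosis, and which is right is not known. By the labels, genotype cannot be told apart from tissue in comparisons with lesions. By the series text, it cannot be told apart from surgery in comparisons with sham uterus. The mice at 3 months were also older than those at 1 month.

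Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-tests, group means with no other term). Comparisons among uterine groups used the 16 uterine libraries, with 21208 genes tested, and comparisons with lesions used all 24 libraries, with 22249 genes tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE). Levels are read counts scaled to library size (CPM, with TMM factors), given as mean ± SD over 4 libraries. Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group. In no comparison did the median log2 fold change over all genes move by more than 0.1.

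40 gene lists with 703 genes (uterine function and steroid response, cell types that the tissue could hold, immune and stress programmes) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A list needed 5 tested members. Members were also counted by their edgeR p adjusted over the list alone.

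The groups, comparisons, tests, lists, most alternatives and the rule for naming genes were chosen before the data were examined. In the 4 main comparisons the rule named a panel of 7 uterine genes (Pgr, Esr1, Ihh, Hand2, Lif, Foxa2 and Ltf), the 4 largest rises and 4 largest falls among called genes whose groups did not overlap and whose mean log2 CPM was at least 1, and up to 3 called members of each of the 5 lists with the smallest p and up to 2 of every other list described. Predicted genes, receptor segments and pseudogenes were left out. Other comparisons named 3 rises and 3 falls. A gene outside the rule is said to be chosen after its values were seen.

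The procedure was tested on counts simulated from the means and dispersions fitted to these data, with known changes added. Changes were put only into genes above a minimum fitted count, so recovery over all tested genes can be lower. Library-wide differences within a group, such as other tissue in a lesion, were not simulated. Of 100 genes given a 4-fold change, 92, 94, 90 and 85 were called in the main comparisons (eutopic against sham at 1 and 3 months, lesions against eutopic at 1 and 3 months). Of 100 genes given a 2-fold change, 75, 74, 55 and 57 were called. Between 2 and 8 unchanged genes were called in each comparison, and 0 genes were called with the wrong sign.

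The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, limma voom with sample weights, only the compared groups in the fit, all 24 libraries in the fit, a term for the replicate number, and each library left out in turn. After the data were seen, fits without single lesion or sham libraries were added because their transcripts pointed to other tissue or to another state. All 24 libraries and every column of the table were used.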

Results

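Read counts per gene were measured in 24 libraries of mouse uterus or endometriotic lesions on pregnancy day 3.5. There were 4 libraries each of sham uterus, eutopic uterus and lesions at 1 month after surgery, and 4 of each at 3 months. The labels call all mice at 1 month fertile, and at 3 months call the sham mice fertile and the mice with endometriosis subfertile. Total counts per library ran from 5.36e+07 to 5.89e+07 in sham, 5.43e+07 to 5.88e+07 in eutopic uterus, 4.51e+07 to 5.91e+07 in lesions at 1 month, and from 4.69e+07 to 5.94e+07 in sham, 4.59e+07 to 5.29e+07 in eutopic uterus, 5.21e+07 to 5.44e+07 in lesions at 3 months.

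Libraries of a group resembled each other least in lesions at 3 months. Across genes, which are not independent replicates, the correlation of log2 CPM between libraries of a group was 0.978 to 0.988 in sham at 1 month, 0.981 to 0.990 in eutopic at 1 month and 0.978 to 0.986 in eutopic at 3 months. It was 0.958 to 0.990 in sham at 3 months, 0.959 to 0.984 in lesions at 1 month and 0.837 to 0.975 in lesions at 3 months. Pairs with sham library 4 at 3 months reached at most 0.968, and the other sham pairs of that time at least 0.980. Pairs with lesion library 2 at 1 month reached at most 0.969, and the other lesion pairs of that time at least 0.979. The first principal component held 44.8% of the variance and the second 16.01%.

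**Figure D1:**
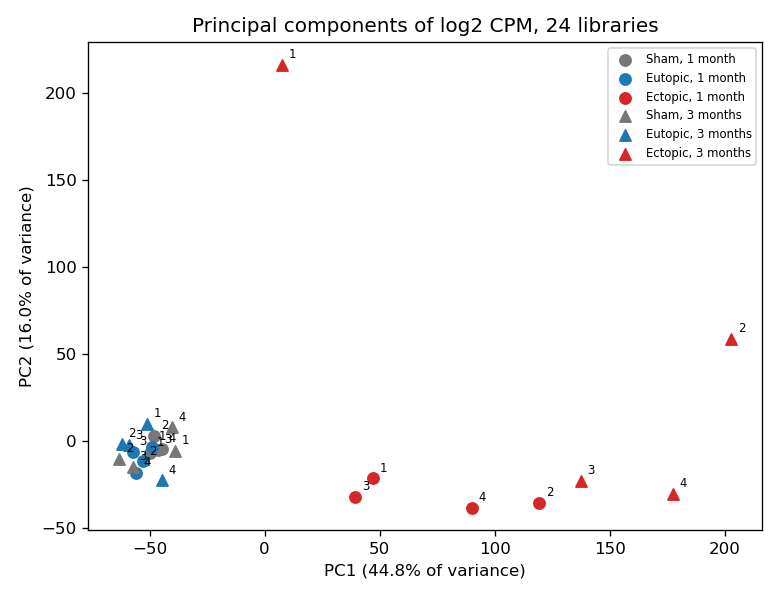
Each point is 1 of the 24 libraries, placed by its score on the first principal component (44.8% of variance, horizontal axis) and the second (16.01%, vertical axis) of log2 CPM. Colour marks the tissue (sham, eutopic or lesion) and shape marks the time after surgery. Lesions at 3 months spread more widely than any other group.

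Several lesion libraries carried transcripts typical of other organs. Lesion library 1 at 3 months had ovarian steroid synthesis genes at a summed 29772 CPM, against 119 to 168 CPM in eutopic uterus at that time, and Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, stood at 7557 CPM in it. Skeletal muscle genes summed to 62147, 20380 and 10987 CPM in lesion libraries 2, 3 and 4 at 3 months and to 7.24 CPM in library 1, against 117 to 177 CPM in eutopic uterus. Library 2 also held 4982 CPM of adipocyte genes, against 139 to 279 CPM in eutopic uterus. At 1 month, lesion library 2 held 68928 CPM of liver and pancreas genes, where eutopic libraries held 12.6 to 15.1 CPM, and Ctrb1, a pancreatic protease chosen after its values were seen, was at 25637 CPM in it. T cell genes summed to 23.5 CPM in lesion library 1 at 3 months, below the 42.7 to 99.2 CPM of eutopic uterus, and to 468 to 1218 CPM in the other lesion libraries of that time. Many list counts for lesions against eutopic uterus are therefore given again without library 2 at 1 month, or without libraries 1 and 2 at 3 months, a choice made after seeing the data.

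**Figure D2:**
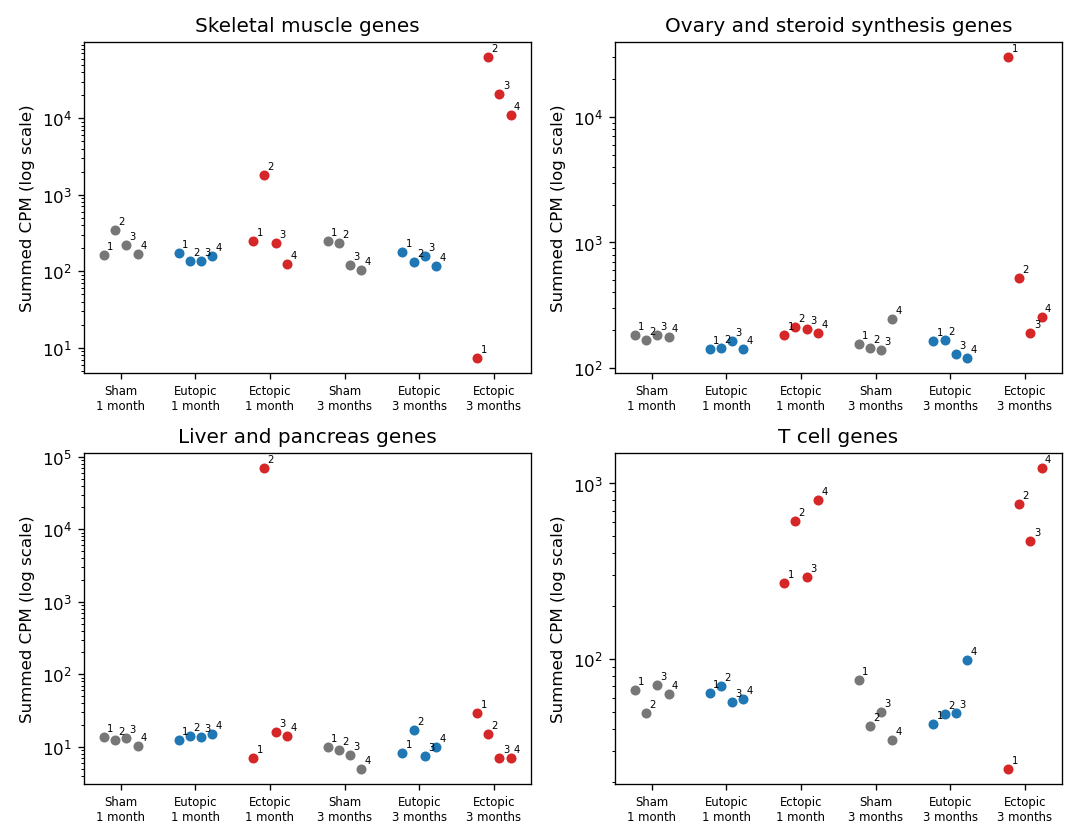
Each point is the summed CPM of skeletal muscle, ovary, liver and pancreas or T cell genes in 1 library (vertical axis, log scale), by group. Ovary genes reach 29772 CPM in lesion library 1 at 3 months and skeletal muscle genes 62147 CPM in library 2.

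Does the uterus of mice with endometriosis differ from sham uterus while the mice are still fertile? At 1 month Ifi202b (ENSMUSG00000026535.10), an interferon-inducible member of a gene family that senses cytosolic DNA, rose from 0.0599 ± 0.0203 CPM in sham to 11.2 ± 0.708 CPM in eutopic uterus (SD, n = 4 each). Its log2 fold change was 7.49 ± 0.42 SE (edgeR, adjusted p = 1.8e-07), and each of the 4 eutopic libraries lay above each sham library. In lesions at 1 month it was at 18.2 ± 5.48 CPM. Gm13736 (ENSMUSG00000082908.5), a processed pseudogene named because it was the only other gene called, rose by 4.47 ± 0.33 (adjusted p = 4.8e-06). These were the 2 genes called of 21208, both higher, while 1023 genes had an unadjusted p under 0.05 where 1060 would by chance. DESeq2 called 14 genes and limma voom 38, and both sets held these 2.

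The uterine panel did not pass at 1 month. Lif, the cytokine that opens the uterus to implantation, was at 9.26 ± 2.37 CPM in eutopic and 18.8 ± 4.58 CPM in sham uterus (SD, n = 4), a log2 difference of -1.03 ± 0.45 with an adjusted p of 0.879 in edgeR. Pgr differed by -0.36 ± 0.29, Esr1 by -0.16 ± 0.20, Hand2 by -0.14 ± 0.13, Ihh by 0.06 ± 0.30 and Ltf by 1.39 ± 0.70. Foxa2 differed by -0.03 ± 0.21, and its sign turned without eutopic library 1 or 2 (0.04 and 0.01) and without sham library 1 or 4 (0.01 and 0.08).

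8 of 39 lists passed in eutopic against sham uterus at 1 month. Luminal epithelium genes stood higher together, with a median log2 difference of 0.51 and 16 of 16 members positive, and fibrosis and matrix genes stood lower, with a median of -0.24 and 4 of 26 positive (adjusted p = 3.8e-05 each, and adjusted p = 0.725 each with an estimated correlation). Mitochondrial transcripts (0.24), mesothelium genes (0.45) and interferon response genes (0.17) were also higher. Red blood cell (-0.76), lymphatic endothelium (-0.25) and B and plasma cell genes (-0.26) were lower. No member of these lists was called over all genes (0 in edgeR), and adjusted over the list alone 1 lymphatic gene was lower. With an estimated correlation the smallest adjusted p of any list was 0.725, so 0 lists passed, and without eutopic library 3 the count was 13.

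At 3 months, when the mice with endometriosis were subfertile, eutopic and sham uterus could not be told apart gene by gene. edgeR called 0 of 21208 genes, with 1007 at an unadjusted p under 0.05 and a smallest adjusted p of 0.379, DESeq2 called 11 and limma voom 4. Hand2, a stromal progesterone target that restrains epithelial growth, was at 82.6 ± 8.72 CPM in eutopic and 68.4 ± 12.3 CPM in sham uterus (SD, n = 4), a log2 difference of 0.27 ± 0.13. Pgr differed by -0.42 ± 0.29, Esr1 by -0.11 ± 0.20, Ihh by -0.16 ± 0.30, Lif by -0.19 ± 0.45, Foxa2 by 0.04 ± 0.21 and Ltf by -0.56 ± 0.68. The sign turned without sham library 4 for Pgr (0.01), Esr1 (0.08) and Foxa2 (-0.13), without eutopic library 4 for Esr1 (0.00455) and Lif (0.11), without eutopic library 3 for Lif (0.07) and Foxa2 (-0.05), without sham library 3 for Lif (0.02), without sham library 2 for Ihh (0.14), and without eutopic library 1 or sham library 1 for Foxa2 (-0.07 and -0.03). Limma voom turned it for Esr1 (0.09) and Foxa2 (-0.17).

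11 of 39 lists passed in eutopic against sham uterus at 3 months. Cell cycle genes stood lower, with a median log2 difference of -0.33 and 0 of 24 positive (adjusted p = 1.8e-05, and adjusted p = 0.859 with an estimated correlation), and lipid and cholesterol genes stood lower, with a median of -0.24 (adjusted p = 0.00091, and 0.859 with an estimated correlation). Mast cell and eosinophil genes stood higher with a median of 0.59 (adjusted p = 0.00011, and adjusted p = 0.473 with an estimated correlation), and progesterone target genes with a median of 0.25 (adjusted p = 0.00011, and adjusted p = 0.767 with an estimated correlation). Ciliated cell, macrophage, stroma, complement, T cell and interferon genes were higher too and unfolded protein response genes lower. 0 members were called in edgeR in any of these 11 lists, either over all genes or adjusted over the list alone. Sham library 4 carried more estrogen target transcripts than the other sham libraries, by a median log2 difference of 1.06, and more cell cycle transcripts, by 0.86. Without it 5 lists passed. They were the ciliated cell, mast cell and eosinophil, interferon and unfolded protein response lists and, newly, lymphatic endothelium genes, which were lower (-0.25). The cell cycle list had a median of -0.06 (adjusted p = 0.312), and the lipid, progesterone target, macrophage, stroma, complement and T cell lists did not pass either (adjusted p = 0.691, 0.0530, 0.610, 0.263, 0.526 and 0.567). With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.185. Without sham library 3 the count was 6 and without sham library 1 it was 17.

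Did the difference between eutopic and sham uterus change from 1 to 3 months? Ifi202b did, with a change of -7.99 in the log2 difference, since it was at 0.0248 ± 0.0193 CPM in eutopic and 0.0342 ± 0.0286 CPM in sham uterus at 3 months (SD, n = 4), and Gm13736 did, with -4.14 ± 0.45 (adjusted p = 0.0013). These were the 2 genes called in the test of the difference, both lower, where DESeq2 called 8 and edgeR with all 24 libraries 0. Since edgeR called 0 genes at 3 months, its calls at 1 month (2) and 3 months could not overlap. The DESeq2 calls at 1 and 3 months shared 1 gene. Across the 21208 genes, which are not independent replicates, the fold changes at both times correlated with r = 0.142.

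What sets lesions apart from the eutopic uterus? At 1 month lesions carried more lymphocyte transcripts. Cd4 (ENSMUSG00000023274.15), the coreceptor of helper T cells, averaged 47.0 ± 25.9 CPM in lesions and 3.02 ± 1.25 CPM in eutopic uterus (SD, n = 4 each), a log2 fold change of 3.96 ± 0.71 SE (edgeR, adjusted p = 0.0016). Foxp3, the transcription factor of regulatory T cells, rose by 5.17 ± 0.97, and Ms4a1, which encodes the B cell antigen CD20, rose by 7.53 ± 0.88 (adjusted p = 5.6e-05). Each of the 4 lesion libraries exceeded each eutopic library for these 3 genes. Of 18 T cell genes, 17 rose and 0 fell (18 adjusted over the list alone), and of 15 B and plasma cell genes, 11 rose and 0 fell (13 adjusted over the list alone). Without lesion library 2, 15 and 9 rose. The adjusted p was 6.9e-10 for T cell and 1.3e-09 for B and plasma cell genes, and 0.539 for both with an estimated correlation.

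Myeloid, complement and interferon genes rose in lesions at 1 month too. Of 20 macrophage genes 15 rose and 0 fell (16 adjusted over the list alone, 14 without lesion library 2), led by Marco, a scavenger receptor (8.87 ± 1.45), Gpnmb, a glycoprotein of phagocytes loaded with lipid (5.40 ± 0.94), and Msr1, another scavenger receptor (3.53 ± 0.64). Of 20 complement genes 13 rose and 0 fell (16 adjusted over the list alone, 13 without library 2), among them C7 (3.55 ± 0.54) and C2 (1.43 ± 0.26). Of 23 interferon response genes 12 rose and 0 fell (20 adjusted over the list alone, 8 without library 2), among them Oas3 (3.63 ± 0.82). Of 28 cytokine genes 21 rose and 0 fell (21 adjusted over the list alone, 15 without library 2), among them Cxcl13, the chemokine that draws B cells into follicles (7.76 ± 1.14), and Il1a (6.09 ± 0.93). Of 14 dendritic cell and MHC class II genes 12 rose and 0 fell (12 adjusted over the list alone, 9 without library 2), with Ciita, their master regulator, up by 3.41 ± 0.68. Of 13 neutrophil genes 8 rose and 0 fell (10 rose and 1 fell adjusted over the list alone), among them Mmp8 (5.83 ± 1.06), and without library 2, 4 rose and 1 fell. These lists passed, with adjusted p from 1.8e-08 for macrophage to 0.00067 for neutrophil genes, and from 0.539 to 0.544 with an estimated correlation.

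Glandular genes fell in lesions at 1 month. Cxcl15, a chemokine of uterine glands, fell from 65.2 ± 11.5 to 1.74 ± 1.59 CPM (SD, n = 4 each), a log2 fold change of -5.22 ± 0.81, and Foxa2, which glands need to form and to secrete Lif, by -2.79 ± 0.68 (edgeR, adjusted p = 0.00062 and 0.0085). Of 16 gland genes 1 rose and 4 fell (3 and 7 adjusted over the list alone, 0 and 4 without lesion library 2), and the list passed (adjusted p = 0.0085, and adjusted p = 0.539 with an estimated correlation). Pgr (0.00 ± 0.57), Esr1 (-0.42 ± 0.26), Ihh (-0.90 ± 0.65), Hand2 (-0.82 ± 0.48) and Lif (-0.50 ± 0.56) were not called. With only the compared groups in the fit, Hand2 (adjusted p = 0.0162) and Ihh (adjusted p = 0.0209) were called lower, and limma voom called both (adjusted p = 0.00096 and 0.00756). A replicate-number term in the fit of the compared groups called Esr1, Ihh, Hand2 and Lif lower (adjusted p = 0.0143, 0.0256, 0.0111 and 0.0492). The labels do not pair samples by that number. Ltf, the estrogen-driven lactoferrin gene, was higher by 3.64 ± 1.20 (adjusted p = 0.037), but its adjusted p was 0.0843 with no filter, 0.0769, 0.101, 0.0980 and 0.0526 without eutopic library 1, 2, 3 or 4, and 0.0753, 0.0503 and 0.0780 without lesion library 2, 3 or 4. For Pgr the sign turned under 9 of these settings, with values from -0.00299 with DESeq2 size factors to -0.11 without lesion library 1.

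Among other groups at 1 month, 7 of 26 fibrosis and matrix genes rose and 0 fell (8 adjusted over the list alone, 6 without lesion library 2), including Tnc, a matrix glycoprotein of wound repair (3.10 ± 0.48), and Tgfb3 (1.08 ± 0.19), with an adjusted p of 0.00046, and 0.650 with an estimated correlation. Of 20 lipid and cholesterol genes 6 rose and 0 fell, with Scd1, a fatty acid desaturase, up by 3.21 ± 0.75 (adjusted p = 0.00017 for the list, and 0.605 with an estimated correlation). Of 19 iron and oxidative stress genes 7 rose and 2 fell (4 and 1 without library 2), with Hmox1, which degrades heme, up by 1.86 ± 0.28 (adjusted p = 0.033 for the list, and 0.539 with an estimated correlation). Of 14 adipocyte genes 3 rose (6 adjusted over the list alone, adjusted p = 0.00017, and 0.544 with an estimated correlation), of 17 unfolded protein response genes 4 rose (7 adjusted over the list alone, and without library 2, 1 rose and 1 fell, adjusted p = 0.0072, and 0.544 with an estimated correlation), of 24 cell cycle genes 2 rose (0 adjusted over the list alone, 0 without library 2, adjusted p = 0.0019, and 0.789 with an estimated correlation), and of 24 estrogen target genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.033, and 0.748 with an estimated correlation). With only the compared groups in the fit 11 fibrosis and matrix, 14 lipid, 9 iron, 6 adipocyte, 6 unfolded protein response, 13 cell cycle and 12 of 23 estrogen target genes rose, and 3 iron and 2 estrogen target genes fell. Wnt4, a progesterone-responsive signal of the decidua, rose by 3.07 ± 0.59, and Sfrp1, a secreted Wnt antagonist, by 2.79 ± 0.37. The largest falls were in Cyp3a59 (-7.45 ± 0.79) and Cyp3a57 (-5.96 ± 0.69), monooxygenases, in Adarb2 (-7.37 ± 1.20) and in Hrk, a promoter of apoptosis (-5.68 ± 0.86). The largest rises were Pnliprp1, a pancreatic lipase relative (16.26 ± 3.15), Ngp, a neutrophil granule gene (at least 1084-fold), Barx1, a homeobox gene (at least 470-fold), and Pvalb, a calcium buffer of muscle (8.59 ± 16.8 CPM in lesions, 1 count in eutopic uterus). Ngp was at 73.0 CPM in lesion library 2 and at 0.193 to 1.05 CPM in the others. Without lesion library 2, the log2 fold change was 5.16 for Pnliprp1, and Pvalb was no longer called (adjusted p = 0.281). Limma voom did not call Pnliprp1 (adjusted p = 0.134) or Pvalb (adjusted p = 0.240), and the fit of only the compared groups did not call Ngp (adjusted p = 0.0953).

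In all, edgeR called 4584 of 22249 genes between lesions and eutopic uterus at 1 month, 2647 higher and 1937 lower, and 2680 without lesion library 2. The count was 2571 without lesion library 4, 2623, 2849 and 2824 without eutopic library 2, 3 or 4, and 10008 with limma voom. Of 40 lists 16 passed, 15 higher and 1 lower, and 0 with an estimated correlation.

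**Figure D3:**
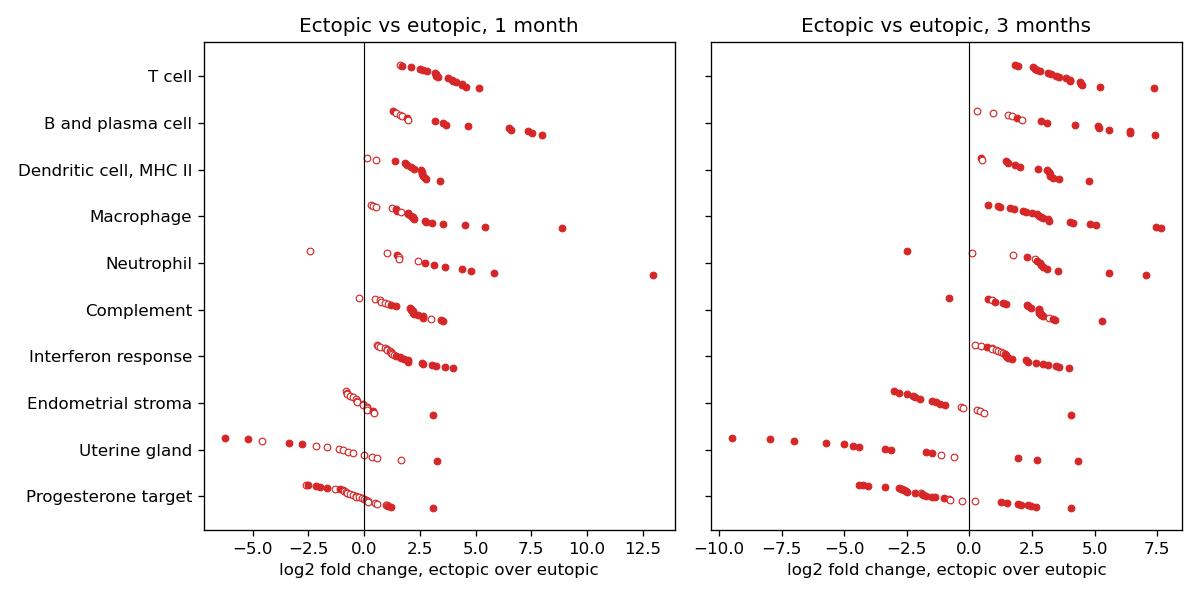
Each point is a gene of a list, placed by its log2 fold change of lesions over eutopic uterus (horizontal axis) at 1 month (left) and 3 months (right), filled where the gene was called. Of 18 T cell genes 17 are filled at 1 month and 18 at 3 months (n = 4 libraries per group).

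At 3 months several hormone-responsive genes were lower in lesions. Hand2 (ENSMUSG00000038193.5) fell from 82.6 ± 8.72 CPM in eutopic uterus to 11.6 ± 9.14 CPM in lesions (SD, n = 4 each), a log2 fold change of -2.84 ± 0.51 SE (edgeR, adjusted p = 0.00027). Esr1, the estrogen receptor alpha gene, fell from 504 ± 119 to 167 ± 74.0 CPM, by -1.59 ± 0.27 (adjusted p = 0.00014), and Pgr, the progesterone receptor gene, from 219 ± 37.2 to 60.8 ± 70.8 CPM, by -1.85 ± 0.59 (adjusted p = 0.017). Hsd11b2, which inactivates glucocorticoids, fell by -4.06 ± 0.46 and Foxa2 by -3.37 ± 0.70. Each of the 4 lesion libraries lay below each eutopic library for these 5 genes. Without lesion libraries 1 and 2 the log2 fold changes were -2.17 ± 0.27 for Hand2, -1.25 ± 0.29 for Esr1, -1.01 ± 0.40 for Pgr (adjusted p = 0.0495), -3.68 ± 0.44 for Hsd11b2 and -3.01 ± 0.73 for Foxa2. Pgr was at -2.99 without lesion library 3 and was not called with only the compared groups in the fit (adjusted p = 0.171).

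Ihh, the epithelial signal to the stroma, was lower by -1.91 ± 0.66 (adjusted p = 0.027) and by -2.83 ± 0.48 without lesion libraries 1 and 2. Its adjusted p was 0.0514 with no filter, 0.0635 and 0.0753 without lesion library 3 or 4, and 0.193 with only the compared groups, and its log2 fold change was -3.32 without lesion library 1 and -3.14 in limma voom. Lif (-0.62 ± 0.56) and Ltf (2.64 ± 1.15, adjusted p = 0.072) were not called. Ltf was called without lesion libraries 1 and 2 (3.58 ± 0.80, adjusted p = 0.0015), without either of them (adjusted p = 0.0316 and 0.0154) and by DESeq2 (adjusted p = 0.0197), while without lesion library 3 Ltf was at 1.42 (adjusted p = 0.322). Lif was at 0.03 without both and at 0.48 in limma voom.

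The lists that hold these genes moved with them. Of 30 progesterone target genes 8 rose and 17 fell (8 and 18 adjusted over the list alone, 5 and 17 without lesion libraries 1 and 2). The risers included Cebpb, a transcription factor of decidualization (2.07 ± 0.25), and Gpx3, a secreted peroxidase (1.92 ± 0.26). Of 16 stroma genes 1 rose and 10 fell (1 and 10 adjusted over the list alone, 1 and 11 without both libraries). Nr2f2, a stromal nuclear receptor, was among the fallers (-1.49 ± 0.25). The riser was Wnt4 (4.05 ± 0.61, and 3.47 ± 0.62 without both libraries). Of 16 gland genes 3 rose and 11 fell (3 and 11 adjusted over the list alone, 3 and 7 without both libraries), with Cxcl15 down by -5.72 ± 0.83. Of 15 smooth muscle genes 1 rose and 10 fell (2 and 10 adjusted over the list alone, 0 and 7 without both libraries), with Smtn at -1.50 ± 0.26. Of 16 luminal epithelium genes 0 rose and 4 fell (0 and 4 adjusted over the list alone), among them Calb1, a calcium-binding protein of the receptive epithelium (-4.46 ± 0.86), and Lpar3, a lysophospholipid receptor needed for embryo spacing (-3.25 ± 0.60). Luminal genes summed to 154 and 59.5 CPM in lesion libraries 1 and 2 and to 1552 and 1067 CPM in libraries 3 and 4, and without libraries 1 and 2, 3 rose and 4 fell. With only the compared groups in the fit 5 rose and 12 fell of the progesterone target genes, 1 and 4 of the stroma genes, 2 and 4 of 14 gland genes, 0 and 1 of the smooth muscle genes and 0 and 2 of the luminal genes. The adjusted p of these 5 lists ran from 0.00038 to 0.0037, and the adjusted p of each was 0.513 with an estimated correlation. Estrogen target genes had a positive median (0.76) where the list test pointed down (adjusted p = 0.709), with 7 higher and 4 lower of 24. Without lesion libraries 1 and 2, 9 were higher and 4 lower with a median of 1.32, and with only the compared groups 1 of 21 was higher and 4 lower.

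Immune transcripts rose in lesions at 3 months, but not all of them in lesion library 1. Of 20 macrophage genes 20 rose (20 adjusted over the list alone, 18 without lesion libraries 1 and 2), with Gpnmb at 7.45 ± 1.03 and Msr1 at 4.82 ± 0.68. Of 18 T cell genes 18 rose (18 adjusted over the list alone, 18 without both libraries), with Foxp3 at 7.38 ± 1.11 and Cd4 at 4.47 ± 0.73. Gpnmb, Msr1, Foxp3 and Cd4 exceeded the eutopic range in 3 of 4 lesion libraries and lay within it in library 1. Of 20 complement genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, 17 and 0 without both libraries), with C7 at 5.28 ± 0.58 in 4 of 4 libraries. Of 15 B and plasma cell genes 10 rose (13 adjusted over the list alone, 14 without both libraries), with Ms4a1 at 7.43 ± 0.88, but they summed to 135 CPM in library 1, below the 1387 to 3316 CPM of eutopic uterus. Of 23 interferon response genes 15 rose (18 adjusted over the list alone, 22 without both libraries). Of 28 cytokine genes 22 rose (22 adjusted over the list alone, 22 without both libraries), with Cxcl13 at 8.81 ± 1.21. Of 14 dendritic cell and MHC class II genes 13 rose (13 adjusted over the list alone, 12 without both libraries), with Ciita at 3.56 ± 0.68. Of 13 neutrophil genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with Mmp8 at 7.06 ± 1.10. With only the compared groups in the fit 9 macrophage, 9 T cell, 9 complement, 7 B and plasma cell, 2 interferon response, 10 cytokine, 4 dendritic cell and 2 neutrophil genes rose. The adjusted p of these 8 lists ran from 2.6e-06 to 0.014, and from 0.513 to 0.631 with an estimated correlation.

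Glycolysis, iron and lipid genes rose in lesions at 3 months. Of 18 hypoxia and glycolysis genes 13 rose and 0 fell (14 and 1 adjusted over the list alone, 14 without lesion libraries 1 and 2), with Aldoa, the aldolase of glycolysis that is abundant in muscle, at 2.67 ± 0.34 and Bnip3, a hypoxia-induced mitophagy receptor, at 1.49 ± 0.23. Lesion libraries 3 and 4 also held 20380 and 10987 CPM of muscle genes, so leaving out libraries 1 and 2 did not remove muscle transcripts. Whether muscle accounts for the glycolysis rise was not tested. Of 19 iron and oxidative stress genes 12 rose and 1 fell (14 and 1 adjusted over the list alone, 9 and 2 without both libraries), with Hmox1 at 134 ± 46.5 CPM in lesions (SD, n = 4), up by 3.17 ± 0.29 (adjusted p = 6.6e-07). Of 20 lipid and cholesterol genes 15 rose and 0 fell (15 adjusted over the list alone, 10 and 1 without both libraries). Cell cycle genes fell: 0 rose and 8 of 24 fell (7 adjusted over the list alone, 1 and 4 without both libraries), with Tyms, which makes thymidylate for DNA synthesis, at -1.41 ± 0.22. Of 8 lymphatic endothelium genes 5 rose (8 adjusted over the list alone), with Pdpn at 1.70 ± 0.28, and of 17 unfolded protein response genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with Atf3 at 3.68 ± 0.63. Skeletal muscle genes rose in 14 of 14 (14 adjusted over the list alone, 14 without both libraries), ovary genes in 11 of 12 (11 adjusted over the list alone, 5 without both libraries, where 2 fell) and adipocyte genes in 8 of 14 (10 adjusted over the list alone, 4 without both libraries). With only the compared groups in the fit 9 hypoxia and glycolysis, 8 iron, 4 lipid, 5 lymphatic, 4 unfolded protein response, 5 ovary and 4 adipocyte genes and 7 of 9 skeletal muscle genes rose, and 1 cell cycle and 1 unfolded protein response gene fell. The adjusted p of these lists ran from 1.2e-05 for skeletal muscle to 0.025 for unfolded protein response genes, and from 0.459 to 0.559 with an estimated correlation.

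The largest rises at 3 months were muscle genes, the myosin heavy chains Myh4 (4326 ± 5451 CPM in lesions, 1 count in eutopic uterus), Myh1 (1486 ± 1722 CPM, 1 count) and Myh2 (at least 23441-fold) and the adenylate deaminase Ampd1 (at least 10510-fold). The largest falls were Cyp3a59 (at least 549-fold lower), Spink1, a trypsin inhibitor (-9.48 ± 2.59), Cyp3a57 (-7.73 ± 0.78) and Pla2g10, a secreted phospholipase (-7.55 ± 1.01). Spink1 was not called in limma voom (adjusted p = 0.346) or without lesion libraries 1 and 2 (adjusted p = 0.0691). In all, edgeR called 9007 of 22249 genes, 5200 higher and 3807 lower, and 3157 with only the compared groups in the fit. A replicate-number term in the fit of the compared groups left 494 called genes. Of 40 lists 22 passed, 16 higher and 6 lower, 24 without lesion libraries 1 and 2, and 0 with an estimated correlation.

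**Figure D4:**
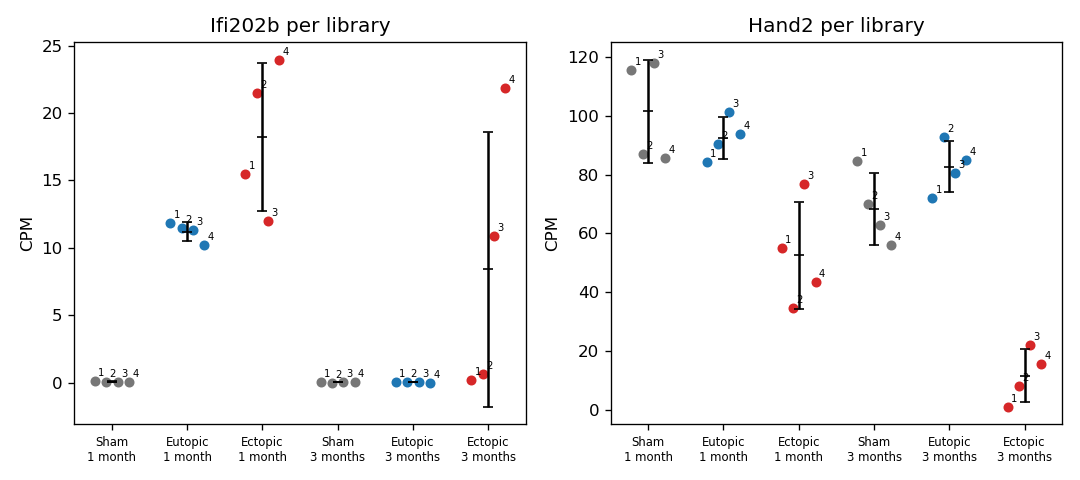
Each point is the CPM of Ifi202b (left) or Hand2 (right) in 1 library, with bars for the mean and SD of 4 libraries. Ifi202b averages 0.0599 CPM in sham and 11.2 CPM in eutopic uterus at 1 month, and Hand2 averages 82.6 CPM in eutopic uterus and 11.6 CPM in lesions at 3 months.

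How did lesions change from 1 to 3 months, relative to the eutopic uterus? The log2 fold change of Tyms moved by -1.32, of Aldoa by 2.42, of Bnip3 by 1.60 and of Pla2g10 by -6.15 ± 1.19 (edgeR, adjusted p = 0.030). Cell cycle genes shifted down as a list, with a median change of -1.17, 0 of 24 positive and 1 member called (21 adjusted over the list alone), at an adjusted p of 7.6e-16, and 0.335 with an estimated correlation. Stroma genes shifted down by a median of -0.96 with 0 members called (3 adjusted over the list alone, adjusted p = 1.3e-05, and 0.335 with an estimated correlation). The largest shifts were Akr1cl (11.10 ± 2.42), Ifi202b (7.61 ± 1.38) and Igfn1 (7.24 ± 1.54) upward and Cpb1, a pancreatic carboxypeptidase (-14.39 ± 2.99), Pla2g10 and Slc51a (-5.82 ± 1.26) downward. Akr1cl was at 5.07 without lesion library 1 at 3 months and 3.42 in limma voom (adjusted p = 0.213), and was not called without lesion libraries 1 and 2 (adjusted p = 0.287). Cpb1 was at -3.52 without lesion library 2 at 1 month and -5.54 in limma voom (adjusted p = 0.692). Limma voom did not call Pla2g10 or Slc51a (adjusted p = 0.297 and 0.238). The shift of Ifi202b came with a fall in eutopic uterus from 11.2 to 0.0248 CPM, while lesions went from 18.2 to 8.40 ± 10.2 CPM. Akr1cl, Cpb1, Igfn1 and Slc51a were not called with no filter (adjusted p = 0.0812, 0.0689, 0.0674 and 0.0667) or with only the compared groups (adjusted p = 0.159, 0.154, 0.159 and 0.0640). Ifi202b was not called with only the compared groups (adjusted p = 0.113) or without lesion library 1 or 3 at 1 month (adjusted p = 0.0679 and 0.0649) or eutopic library 3 or 4 at 3 months (adjusted p = 0.0632 and 0.0728). Leaving out single libraries ended the calls of the other 5 as well.

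edgeR called 166 genes in this test of the difference, 98 higher and 68 lower. The count was 29 with no filter, 10 with only the compared groups, 466 with limma voom, 822 with DESeq2 and 274 without lesion libraries 1 and 2 at 3 months. Leaving out 1 library gave 11, 383, 16 and 67 (lesions 1 to 4 at 1 month), 898, 53, 991 and 451 (lesions 1 to 4 at 3 months), 55, 19, 25 and 25 (eutopic 1 to 4 at 1 month) and 33, 34, 15 and 17 (eutopic 1 to 4 at 3 months), so this count rests on single libraries. Calls of lesions against eutopic uterus at both times overlapped: 2269 genes were higher at both, where 619 would be shared by chance, and 1347 lower at both, where 331 would. 0 genes higher at 1 month were lower at 3 months, and 3 lower at 1 month were higher at 3 months. Since the eutopic libraries differ between the times and the genes are not independent, no p is given.

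Against sham uterus, lesions at 1 month showed 17 of 18 T cell, 18 of 23 interferon response and 16 of 20 macrophage genes higher, at list medians of 3.31, 1.64 and 2.24 (adjusted p = 3.4e-11, 3.4e-11 and 7.2e-10, and 0.357, 0.368 and 0.357 with an estimated correlation). Tmprss11a, an epithelial serine protease, fell from 4.53 ± 4.19 CPM to 1 count over the lesions, and Adarb2 fell by -7.48 ± 1.20. Prss29, an implantation serine protease, was at -8.87 ± 2.30 and was not called without lesion library 4 (adjusted p = 0.0521) or in limma voom (adjusted p = 0.0747). Gp2 (339 ± 677 CPM in lesions, 3 counts in sham), Zg16 (14.14 ± 2.89) and Pnliprp2 (10.22 ± 2.03), all abundant in pancreas, had the largest rises and were not called without lesion library 2 (adjusted p = 0.102, 0.0935 and 0.0756) or in limma voom (adjusted p = 0.154, 0.134 and 0.0927). edgeR called 3324 genes, 2100 higher and 1224 lower. The count was 1720 and 1691 without lesion library 2 or 4, 2197, 1892 and 2150 without sham library 2, 3 or 4, 5869 with only the compared groups and 7685 with limma voom. Of 40 lists 17 passed, and 0 with an estimated correlation.

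Against sham uterus at 3 months, 15 of 30 progesterone target genes were lower and 7 higher in lesions (adjusted p = 0.042, and 0.515 with an estimated correlation), 20 of 24 cell cycle genes were lower (adjusted p = 3.3e-06, and 0.515 with an estimated correlation), and 19 of 20 macrophage genes were higher (adjusted p = 3.1e-07, and 0.515 with an estimated correlation). Sham library 4 stood above the other sham libraries in 24 of 24 cell cycle genes, and against eutopic uterus 8 were lower in lesions. Hsd3b1, an enzyme of steroid synthesis, rose at least 1.28e+05-fold, with 6113 CPM in lesion library 1 and 60.0, 1.17 and 1.73 CPM in libraries 2, 3 and 4. It was not called with only the compared groups (adjusted p = 0.0854). Myh4 and Myh1 rose as well, from 3 counts and 1 count in sham. Cyp3a59 (at least 433-fold lower), Cyp3a57 (-7.65 ± 0.78) and Pla2g10 (-6.73 ± 0.99) had the largest falls, and limma voom did not call Pla2g10 (adjusted p = 0.0576). edgeR called 9256 genes, 5155 higher and 4101 lower, and 2414 with only the compared groups. Of 40 lists 22 passed, and 0 with an estimated correlation.

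Over time within a tissue, sham uterus showed 0 called genes between 3 months and 1 month in edgeR, with 2266 at an unadjusted p under 0.05, while DESeq2 called 159, limma voom 1037 and edgeR without sham library 1 at 3 months 427. Cell cycle genes stood higher at 3 months as a list, with a median of 0.53 and 24 of 24 positive (adjusted p = 2.2e-12, and 0.368 with an estimated correlation), and sham library 4 at 3 months stood above the other shams in 24 of 24 by a median of 0.86. Eutopic uterus had 2 called genes, Ifi202b (-8.73 ± 0.47, adjusted p = 9.0e-08) and Gm13736 (-4.05 ± 0.32, adjusted p = 1.4e-05), both lower at 3 months, where DESeq2 called 14 and limma voom 7. Lesions had 2414 called genes, 1442 higher and 972 lower at 3 months. The largest rises were the steroid synthesis genes Hsd3b1 (at least 1.16e+05-fold), Lhcgr (13.24 ± 2.30) and Cyp11a1 (12.35 ± 2.08), of which Lhcgr and Cyp11a1 were at 2.88 and 2.69 without lesion libraries 1 and 2, and the largest falls were Cpb1 (-14.63 ± 2.67), Pnliprp2 (-11.64 ± 2.22) and Pla2g10 (-6.43 ± 0.98), of which Cpb1 and Pnliprp2 were at -3.77 and -3.10 without lesion library 2 at 1 month. The count was 1552 without lesion libraries 1 and 2 at 3 months, 3846 and 3691 without lesion library 1 or 3 at 3 months, 1265 and 1152 without lesion library 1 or 3 at 1 month, 1007 with limma voom and 0 with only the compared groups.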

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

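A sample standing apart from its group of 4 was looked for among the named genes. Of 357 groups tested, 26 held such a library, where chance gives about 1 in 20, or 17.85. The value is the gap to the nearest library over the range of the group. In eutopic uterus at 1 month it was 0.919 for Atp2a1 (library 3, high), 0.886 for Hspe1 (library 1, low), 0.901 for Ltf and 0.950 for Pnlip (library 4, high), 0.838 for Pdpn (library 2, high), and, high in library 1, 0.860 for Itgav, 0.835 for Mbp, 0.846 for Pfkp and 0.866 for Pgr. In lesions at 1 month it was 0.965 for Cela1 and 0.848 for Zg16 (library 2, high, the library with pancreas transcripts) and 0.905 for Hpx (library 4, high). In sham at 3 months it was 0.863 for Ltf (library 1, low). In eutopic uterus at 3 months it was 0.899 for Hsd11b2 (library 3, low), 0.910 for Nr4a1 (library 1, high), 0.960 for Tdgf1 (library 4, high) and 0.890 for Tppp3 (library 4, low). In lesions at 3 months it was 0.836 for Foxp3, 0.860 for Msr1, 0.861 for Myh1 and 0.8295 for Myh4 (library 1, low), 0.954 for Inhba and 0.869 for Wnt4 (library 1, high), 0.842 for Foxa2 and 0.937 for Top2a (library 2, low) and 0.895 for Snai1 (library 3, high).

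Some named genes changed differently at 3 months than at 1 month, by a test of the difference in log2 fold change. For eutopic against sham uterus this was Ifi202b (-7.99). For lesions against eutopic uterus these were Ifi202b (7.61), Pla2g10 (-6.15), Aldoa (2.42), Bnip3 (1.60), Tyms (-1.32), Hdc (-2.32), Akr1cl (11.10), Igfn1 (7.24), Cpb1 (-14.39) and Slc51a (-5.82).

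The tests of the rise of Ifi202b at 1 month were chosen after the result was seen, and the rise of Gm13736 was not tested. Gm13736 was placed on another chromosome than Ifi202b, so it is not among the neighbours counted here. An inherited variant in a mixed background could change genes near Ifi202b, and 7 of its 40 neighbours, 5 lower and 2 higher, had an unadjusted p under 0.05 where 1.91 would by chance. But without the 13 members of its gene family 3 of 27 had, where 1.29 would, so this cannot be told. Reads shared within the family could be a source, and the family neighbours changed by a summed -18.1 CPM against a gain of 11.1 CPM for Ifi202b, so this cannot be told either. A rise of that size shared by other interferon genes is excluded, since the highest upper bound among them was 1.08. This does not exclude a smaller interferon response, as their median log2 difference was 0.17.

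The tests of lesion libraries 1 and 2 at 3 months were chosen after the result was seen. Ovarian tissue in library 1 is a likely source, with 83.3% of ovary genes over 10 times the highest eutopic library. Skeletal muscle in library 2 reached 100% of muscle genes, as it did in libraries 3 and 4, so this share cannot show whether muscle sets library 2 apart. The 2 libraries are excluded as the whole cause of the lower Hand2, which was at -2.17 without them.

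The tests of sham library 4 at 3 months were chosen after the result was seen. Without it 5 lists passed in place of 11. A more estrogen-driven uterus is a candidate explanation, since its estrogen target genes stood higher by a median of 1.06.

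The counts were also compared with those from other splits of the same libraries, a test chosen before the data were examined. For eutopic against sham uterus at 1 month 1 of 35 splits gave as many genes (2 in the real split, at most 0 in another), for lesions against eutopic uterus 1 of 35 at 1 month (4584 and 2) and 1 of 35 at 3 months (9007 and 5499), for lesions against sham 1 of 35 at 1 month (3324 and 0) and 1 of 35 at 3 months (9256 and 5781), and for eutopic uterus over time 1 of 35 (2 and 1). In each of these the real split ranked first, the most that 35 splits can show. The shares were not corrected for the number of counts compared. For the change over time it was 4 of 100 for eutopic against sham (2 and 27) and 3 of 100 for lesions against eutopic (166 and 308). These shares are under 0.05 but do not exclude chance, since other splits called more genes. Chance cannot be excluded for lesions over time (3 of 35, 2414 and 3656). For eutopic against sham uterus at 3 months (35 of 35, 0 and 21) and sham over time (35 of 35, 0 and 410) the real count of 0 fixes the outcome, so the comparison says nothing about chance. Chance cannot be excluded for the counts of lists: eutopic against sham 11 of 35 at 1 month (8 and 12) and 24 of 35 at 3 months (11 and 22), lesions against eutopic 12 of 35 (16 and 22) and 8 of 35 (22 and 28), and lesions against sham 11 of 35 (17 and 24) and 8 of 35 (22 and 26). Splits that called 410 and 21 genes where the real one called 0, and 27 where it called 2, point to a structure of the samples.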

How the results depend on the processing

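Counts of called genes moved with the method, and the cause was not tested. DESeq2 gave 14 (eutopic against sham, 1 month), 11 (3 months), 8 (their change over time), 822 (change of lesions against eutopic), 159 (sham over time), 14 (eutopic over time) and 1 gene shared by the eutopic calls at both times. Limma voom gave 38, 4, 10008 (lesions against eutopic, 1 month), 7685 (lesions against sham, 1 month), 466 (change of lesions against eutopic), 1037 (sham over time), 7 (eutopic over time) and 1007 (lesions over time). Only the compared groups gave 3157 (lesions against eutopic, 3 months), 5869 and 2414 (lesions against sham, 1 and 3 months), 10 (change of lesions against eutopic) and 0 (lesions over time). The replicate-number term, fitted with only the compared groups, gave 494, 0 (lesions against sham, 3 months), 0 and 1 (changes over time) and 0 (lesions over time), so these moves cannot be put down to the term alone. All 24 libraries gave 0 for the change of eutopic against sham, and no filter 29 for that of lesions. Without lesion libraries 1 and 2 at 3 months, a choice made after seeing the data, it was 274, and 1552 for lesions over time. An estimated correlation left 0 lists in all 6 comparisons with lists counted.

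Leaving out 1 library gave 2571 to 4695 genes for lesions against eutopic at 1 month and 7638 to 10858 at 3 months, 1691 to 3233 and 7840 to 10908 against sham, 11 to 991 for the change of lesions against eutopic, 2 to 3 for that of eutopic against sham, 0 to 427 (sham), 2 to 3 (eutopic) and 1152 to 3846 (lesions) over time, 2 to 2 and 0 to 0 for eutopic against sham, and lists of 8 to 13, 5 to 17, 14 to 19, 21 to 25, 17 to 21 and 21 to 22.

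The sign turned for Esr1 (0.0864, limma voom), Foxa2 (-0.17, limma voom) and Ihh (0.0225, replicate-number term) in eutopic against sham at 3 months, for Pgr in lesions against eutopic at 1 month (-0.00299 with DESeq2 size factors, -0.00781 with no filter, -0.00304 with DESeq2, -0.0157 with only the compared groups), and at 3 months for Lif (0.48, limma voom, and 0.0308 without libraries 1 and 2) and Dnah9 (-0.21 without them). Leaving out 1 library gave, in eutopic against sham, Foxa2 -0.0960 to 0.0802 at 1 month and, at 3 months, Pgr -0.57 to 0.0125, Esr1 -0.25 to 0.0831, Ihh -0.45 to 0.14, Lif -0.69 to 0.11 and Foxa2 -0.13 to 0.21, and in lesions against eutopic at 1 month Pgr -0.11 to 0.26. It turned 20 of 1768 values for named genes and ended 140 calls. The replicate-number term, fitted with only the compared groups, turned 1 of 198 such values, ended 88 calls and added 4.

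The labels do not pair samples by number. Asked as a hint from the data, not the design, whether every sample correlates best with its own number, 8 of 8 eutopic and lesion samples did at 1 month (r from 0.0735 to 0.191) and 6 of 8 at 3 months (0.00343 to 0.337).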

Other observations

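Tissue-repair and nerve genes also differed in lesions. Mbp, the myelin basic protein gene, was higher in lesions than in eutopic uterus at 3 months (2.51 ± 0.25 SE). Thbs1, which activates latent transforming growth factor beta, rose by 1.70 ± 0.18 at 3 months and Tgfb1 by 1.94 ± 0.25. Hdc, which makes histamine, fell by -2.93 ± 0.39, and Twist2, a stromal transcription factor, by -2.71 ± 0.43 (edgeR, n = 4 per group).

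Lesions at 3 months might hold less hormone-responsive stroma, or stroma with a lost response. Hand2 was at -2.17 without libraries 1 and 2 and the stroma list fell too, but either reading could lower both. Wnt4, a member of that list, went the other way (4.05 ± 0.61 with all libraries). Stroma genes summed to 2128, 8672, 4473 and 5228 CPM in lesion libraries 1 to 4, against 5804 to 6779 CPM in eutopic uterus. Transcripts of other tissue in these libraries were not accounted for. Counting stromal cells beside in situ staining of Hand2 would separate less stroma from a lost response.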
